A study of Mus musculus with 40 samples.

How the data were processed

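The ascending aorta of male Ldlr-/- mice was dissociated and sorted into ZsGreen1+ and ZsGreen1- cells, the cells of each mouse were marked with a hashtag, and 3 mice of 1 genotype, week and sort were pooled into each 10x library. Of the 40 samples in the labels, 20 are gene expression libraries (2 genotypes, 2 sorts, 5 weeks) and 20 are the matching hashtag libraries, which hold no matrix of their own and were left out. The authors deposited UMI counts per gene and cell, made with Cell Ranger 6.1.2 on the mouse build mm10, already split into 1 matrix per mouse and sort, which makes 60 matrices. Filters on cells before the deposit, the gene annotation release and the deleted part of Perk are not given in the sources used here. The protocol in the labels speaks of pooling the 2 sorts before the 10x step, whereas the titles give a library for each. The shares of cells with ZsGreen1 counts in the report are those of separate sorts, and the libraries were taken as the titles name them. The same hashtag marked a mouse in both sorts for all 30 mice, but the numbers given with the matrices agree between the sorts for only 27. The hashtag was taken as the mouse.

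Each matrix held 32286 genes, of which 32158 were found with a position in GENCODE vM21 (GRCm38), and 12 hashtag features, which were left out of all sums. Cells with at least 500 genes and under 10% mitochondrial counts were kept, 100822 of 110774 (91.0%). Cells of each sort were normalized to a common depth, log-transformed, reduced to 2000 variable genes (without mitochondrial genes, ZsGreen1 and Eif2ak3) and 40 principal components, linked to 15 neighbours and clustered by the Leiden method at resolution 1 (leidenalg 0.10.2, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Genotype and week were not used in clustering, and no correction for libraries was made. A marker led a cluster when found in at least 20% of its cells at a CPM 1.5-fold or more above that of all other kept cells. A cluster took the class with the greatest share of leading markers, at least 3, if no other class had more markers among its 10 leading genes (ranked by fold with 100 CPM added to both sides), and clusters of very low depth were not named. No ZsGreen1+ cluster was named chondrocyte-like at this resolution, and a further step was then added. Modulated ZsGreen1+ clusters led by at least 3 cartilage markers (12 and 14) were clustered again alone, on the same principal components with 15 neighbours at resolution 1. Their parts were named by the same rule, and the chondrocyte-like parts stayed within the modulated class. The marker lists were written before the data were examined, whereas these naming thresholds were set after the clusters were seen. Clusters without a clear class were left out of the classes but not of the sums over all cells of a sort. Scrublet (in scanpy 1.11.5, with scikit-learn 1.9.0) called 284 cells doublets (0.282%), too few for the caller to have worked on these libraries. An alternative therefore removed the cells with the highest 5% of scores (5.53% with ties).

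The mouse was the replicate. Counts were summed per mouse over all kept cells of a sort, or over the cells of a class where a mouse had at least 20, which all 30 mice had except for 2 in endothelial-like and 4 in modulated SMC-like cells. Sums were tested with edgeR 4.0.16 (R 4.3.3; TMM factors, filterByExpr, quasi-likelihood F test, two-sided), with week as a factor in genotype comparisons and genotype as a term in comparisons of weeks 16 and 0, and p values were adjusted by Benjamini and Hochberg (BH) with a threshold of 0.05. The interaction of genotype with week was a single test over the 5 weeks. That of genotype with sort used the sums of both sorts, without a term for the mouse. The SE of a log2 fold change was taken as its size divided by the square root of F, which is approximate. CPM values are means over mice of counts scaled to the depth of the sum (edgeR cpm scale), with the SD between mice. A fold against a group with 0 counts was computed against a floor of 3 counts over the group. Shares of cells per mouse were compared by 100000 permutations of genotype within weeks (two-sided, seed 1), and their 95% interval holds the shifts that this test, run with fewer permutations, does not reject. Shares were related to week by Spearman's rho and Pearson's r, with two-sided p values from as many permutations of the weeks within genotypes.

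The 18 gene lists were written before the data were examined: ATF4 targets of the integrated stress response, ER chaperones and degradation (ATF6 and XBP1 targets), SMC contractile apparatus, modulated SMC and fibrotic matrix, cartilage and mineralisation, cholesterol synthesis (SREBP2 targets), cholesterol efflux and lipid handling (LXR targets), interferon response, inflammatory cytokines and NF-kB, antigen presentation, complement, lysosome and foam cell, immediate early and dissociation, cell cycle, oxidative phosphorylation, NRF2 targets, TGF-beta response and apoptosis. They were tested against all other genes with camera (limma 3.58.1) at a correlation of 0.01 between genes, with BH over the 18 lists. Some genes stand in more than 1 list, such as Spp1, Vcam1, C3 and Atf3. Genes were named by a rule written before the data were examined: in each test the 10 largest increases and the 10 largest decreases among genes past the threshold with a mean log2 CPM of at least 4, without clone-like symbols, then up to 4 members of each list with the smallest p, and Eif2ak3, ZsGreen1 and Myh11 in genotype comparisons. The text prints a part of these. The rule names no gene for the interaction with week, which has no single fold change.

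The contrasts, tests and most alternatives were fixed before the data were examined. The alternatives were stricter cell filters (1000 genes, 5% mitochondrial counts), Leiden resolutions of 0.5 and 2, removal of doublets, no filter on low counts, DESeq2 1.42.0, sums per library, limma-voom per mouse with the library as a random effect (statmod 1.5.0), the share of modulated cells as a covariate, camera with estimated correlations, fry, shares per library, and leaving out each mouse and each week. Added after the data were seen were leaving out each mouse for the shares, the animal as a block, other boundaries of the classes, removal of high doublet scores, and the weeks 0 to 8 and 12 to 16 taken apart. Figures were drawn with matplotlib 3.10.9.

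The tests were tested on simulated data made with the gene means, depths and trended dispersion of these sums. In ZsGreen1+ genotype sums edgeR recovered 90 of 98 genes changed 1.5-fold and 99 of 99 changed 2-fold, with 12 false among 201 calls over 13486 genes. For week 16 against week 0 it recovered 71 of 99 and 88 of 98 in ZsGreen1+ sums (13493 genes), and 14 of 100 and 45 of 98 in macrophage-like sums (10222 genes), so most 1.5-fold changes there go unseen. The interaction with week recovered 13 of 100 and 58 of 98 (13590 genes). When each simulated library was given its own deviation with an SD of 0.2 on the log2 scale, 918 of 1100 genotype calls on mouse sums were false, against 40 of 185 in limma with the library and 5 of 153 on library sums (13494, 13494 and 13672 genes). The 3 mice of a genotype and week share a library. A library deviation therefore counts as a genotype difference in every test on mice without a term for the library.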

Results

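Cells of the ascending aorta, from the root to the distal arch, were profiled by single-cell RNA sequencing (10x 3' chemistry, version 3) in male Ldlr-/- mice, which lack the low-density lipoprotein receptor and become hypercholesterolaemic on a western diet. In the KO mice, Perk was deleted in smooth muscle cells (SMC) by a tamoxifen-induced Cre recombinase under the Myh11 promoter, and the same Cre switched on the fluorescent label ZsGreen1 in SMC of both genotypes. Perk (Eif2ak3, ENSMUSG00000031668, chromosome 6, 70844515 to 70905245 of GRCm38) is the kinase of the endoplasmic reticulum (ER) that slows translation and starts the integrated stress response when unfolded proteins accumulate. For each genotype, 3 mice were taken at each of 5 time points, at the start of the diet and at weeks 4, 8, 12 and 16, which makes 30 mice. Each mouse gave a ZsGreen1+ sort, which holds the SMC lineage, and a ZsGreen1- sort, and 20 libraries each pooled the hashtagged cells of 3 mice of 1 genotype, week and sort. After filtering, 54071 ZsGreen1+ and 46751 ZsGreen1- cells were kept. The ZsGreen1+ cells of a mouse held 11371460 to 30569975 counts in 748 to 2724 cells, and the ZsGreen1- cells 2717303 to 32230763 counts in 440 to 3851 cells. At least 1 ZsGreen1 count was found in 98.8% to 99.96% of the ZsGreen1+ cells of a mouse (median depth 6868 to 16411.5 counts per cell) and in 11.1% to 26.2% of its ZsGreen1- cells (median depth 5407 to 8910 counts).

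Most ZsGreen1+ cells were contractile SMC-like, with 37137 cells led by Myh11, Acta2 and Cnn1, which encode proteins of the contractile apparatus. Another 5254 ZsGreen1+ cells were modulated SMC-like, led by Vcam1, Fn1, Timp1 and Lum, genes of adhesion and extracellular matrix. Of these, 209 cells, in 2 parts of 150 and 59 cells of modulated cluster 12, were led by Col2a1, Acan and Sox9, genes of cartilage. They are called chondrocyte-like and stay counted as modulated. Smaller ZsGreen1+ classes were 2043 pericyte-like, 913 fibroblast-like, 234 macrophage-like and 88 cycling cells, while 8402 cells fell into clusters with no clear class. The ZsGreen1- cells were mainly 16214 fibroblast-like, 15396 macrophage-like, 3856 endothelial-like and 3008 monocyte-like cells, with 2473 in no clear class. The share in no clear class ran from 3.52% to 32.2% of ZsGreen1+ cells and from 1.13% to 7.49% of ZsGreen1- cells between groups. Over all mice it was 14.4% of ZsGreen1+ cells in WT and 17.4% in KO mice (difference 3.00 points, permutation p = 0.0108, BH-adjusted p = 0.0759 over 7 classes). The largest part of it was a pair of ZsGreen1+ clusters, 5 and 6, with contractile markers and with Postn, a matrix gene, among their leading genes, which made up 13.5% of cells in WT and 16.1% in KO mice (difference 2.65 points, permutation p = 0.0226, BH-adjusted p = 0.330 over 19 quantities).

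The study asks whether SMC need Perk to leave the contractile state during atherosclerosis, and the share of modulated cells bears on this question. Modulated SMC-like cells made up 9.91 ± 10.4% of ZsGreen1+ cells in WT mice and 9.48 ± 10.1% in KO mice (mean ± SD, n = 15 each). The difference of -0.426 points had a 95% interval of -3.49 to 2.70. Counting the unnamed clusters 5 and 6 as modulated turned it to 2.22 points (permutation p = 0.265). With diet, this share climbed from 0.638 ± 0.155% in WT and 1.05 ± 0.471% in KO mice at week 0 to 25.3 ± 7.08% and 25.7 ± 9.53% at week 16 (SD, n = 3 each). Macrophage-like cells made up 26.5 ± 16.4% of ZsGreen1- cells in WT and 25.8 ± 17.7% in KO mice (SD, n = 15 each), a difference of -0.725 points with an interval of -4.70 to 3.29. Their share was 7.75 ± 2.69% and 4.40 ± 2.06% at week 0 and 44.7 ± 10.7% and 44.4 ± 8.67% at week 16. Chondrocyte-like cells made up 0.517 ± 0.802% of ZsGreen1+ cells in WT and 0.276 ± 0.778% in KO mice, a difference of -0.241 points with an interval of -0.716 to 0.244. At week 12 they numbered 74 of 4913 cells in WT and 3 of 6625 in KO mice (1.53 ± 0.905% against 0.0367 ± 0.0636%, n = 3 each), and at week 16 they numbered 57 of 5627 and 74 of 5705. None were found at weeks 0 and 4, where 0 of 5961 and 0 of 6885 WT cells allow shares of up to 0.0503% and 0.0436%, and 0 of 5465 and 0 of 4082 KO cells up to 0.0549% and 0.0735%. These limits pool the cells of 3 mice and leave out the spread between mice.

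The genotype labels were permuted within weeks in a two-sided permutation test, which gave p = 0.823 for modulated, 0.332 for chondrocyte-like and 0.712 for macrophage-like shares (BH-adjusted p = 0.823 for each of the 3). Within a week, the exact permutation test of 3 against 3 mice cannot go below p = 0.1, and the chondrocyte-like share at week 12 reached that limit. Across the 30 mice, week correlated with the modulated share (rho 0.967, r 0.876), the macrophage-like share (rho 0.893, r 0.898) and the chondrocyte-like share (rho 0.785, r 0.579). The permutation p was 1e-05, the smallest that 100000 permutations can give, for each of these except r of the chondrocyte-like share, whose p was 1e-04, and adjustment over the 3 relations left none above 1e-04. Rho was 0.949, 0.927 and 0.834 within WT mice and 0.982, 0.851 and 0.756 within KO mice, in the same order. Without the 12 mice of weeks 0 and 16, which lie farthest from the median week, r was 0.854, 0.840 and 0.498 (permutation p = 1e-05, 0.000130 and 0.00386, n = 18). Leaving out mouse KO 1 of week 16 took the chondrocyte-like difference to -0.406 points (permutation p = 0.0476), and leaving out week 12 turned it to 0.0717. The modulated difference turned to 0.379 without week 12 and the macrophage-like one to 0.695 without week 8. Week cannot be separated from the age of the animals or the preparation of the libraries. The permutations exchanged single mice and take them as independent, although the 3 mice of a genotype and week share a library.

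**Figure D1:**
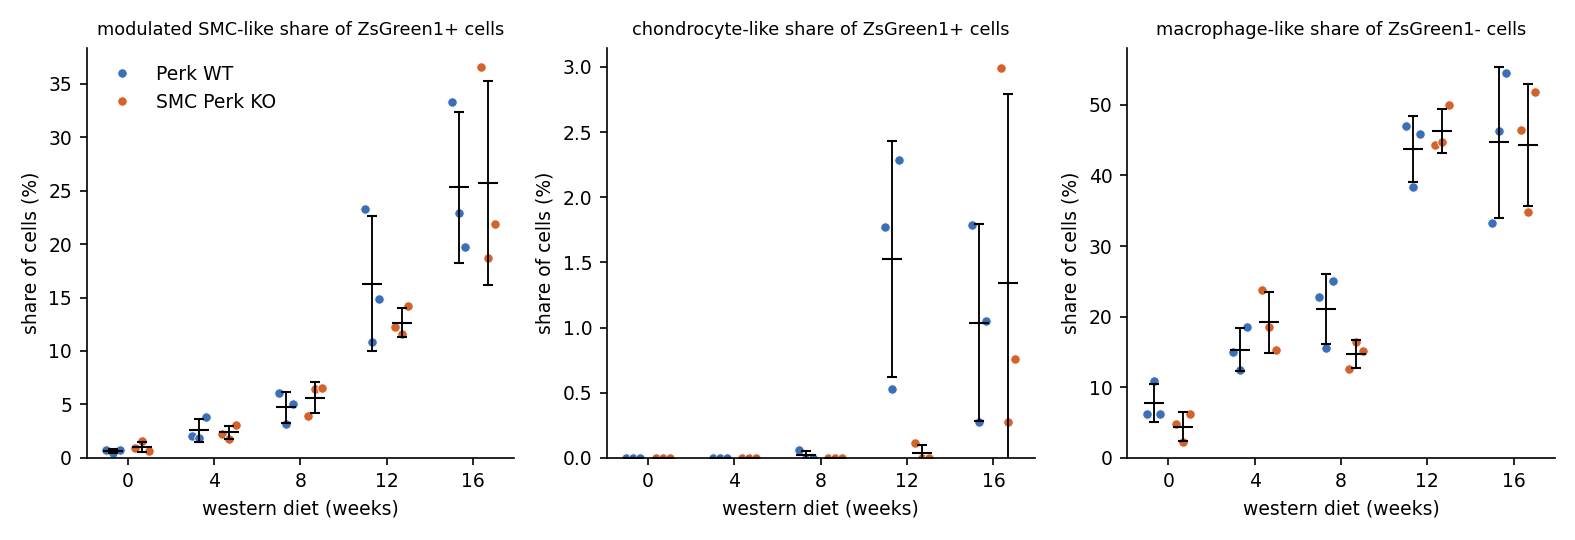
Share of modulated SMC-like, chondrocyte-like and macrophage-like cells, in percent of the cells of the sort, against weeks of western diet. Each point is 1 mouse, and black marks with bars give the mean and SD of the 3 mice of a genotype and week. The means reach 25.3% (WT) and 25.7% (KO) modulated cells at week 16.

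All ZsGreen1+ cells of a mouse were then summed to ask which genes differ between the genotypes when Perk is deleted. Eif2ak3 was lower in KO mice, at 2.47 ± 0.611 CPM (counts scaled to the depth of the sum) against 4.51 ± 0.814 in WT mice (mean ± SD, n = 15 each, as for all genotype values in these sums). Its log2 fold change was -0.85 (SE 0.09, adjusted p = 1.02e-06) and was seen in 5 of 5 weeks. In the ZsGreen1- sort Eif2ak3 stood at 11.2 ± 2.78 CPM in KO and 10.7 ± 2.70 CPM in WT mice. The deleted part of the gene is not given in the sources used here and 3' counts can lie outside it, so this level measures neither recombination nor protein. Myh11 (2194 ± 523 against 2184 ± 267 CPM, log2 fold change 0.00, SE 0.06, adjusted p = 0.992) and ZsGreen1 (log2 fold change 0.08, SE 0.04, adjusted p = 0.220) did not pass the test.

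Higher in KO mice were Zbtb16 (27.6 ± 12.4 against 15.1 ± 3.83 CPM, log2 fold change 0.82, SE 0.15, adjusted p = 0.00128) and Klf15 (log2 fold change 0.61, SE 0.13, adjusted p = 0.00561), transcription factors known to be induced by glucocorticoids, in 5 and 4 of 5 weeks. So were Chordc1 (54.9 ± 9.34 against 40.1 ± 6.32 CPM, log2 fold change 0.47, SE 0.07, adjusted p = 0.000175), a cochaperone of Hsp90, and Hsph1 (log2 fold change 0.46, SE 0.09, adjusted p = 0.00305) and Dnaja1 (log2 fold change 0.46, SE 0.11, adjusted p = 0.0135), which act with Hsp70. Further genes higher in KO mice were Id1 (0.57), a BMP target that blocks differentiation factors, Lpp (0.48), a focal adhesion protein of SMC, Myoz2 (0.51), which binds calcineurin, Socs2 (0.46), a brake on cytokine signalling, and Sntg2 (0.46). Lower in KO mice was Igsf9 (11.5 ± 3.78 against 20.7 ± 7.27 CPM, log2 fold change -0.78, SE 0.13, adjusted p = 0.000715), an adhesion protein, in 5 of 5 weeks. Ide (28.0 ± 7.62 against 43.6 ± 7.50 CPM, log2 fold change -0.64, SE 0.09, adjusted p = 0.000175), the insulin-degrading enzyme, was lower in 4 of 5. Anxa4 (log2 fold change -0.50, SE 0.08, adjusted p = 0.000657), a calcium-dependent membrane-binding protein, lies on the chromosome of Eif2ak3 (ENSMUSG00000029994, chromosome 6, 86736840 to 86793584). Others lower in KO mice were the phosphatase gene Ppm1m (-0.70), Rrad (-0.55), which restrains calcium channels, Pltp (-0.54), a phospholipid transfer protein, Igfbp5 (-0.51), the keratin gene Krt18 (-0.50), Smim5 (-0.53) and Atcayos (-0.52).

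Of 13672 genes tested, 884 passed in ZsGreen1+ sums, 467 higher and 417 lower in KO mice, with a median absolute log2 fold change of 0.23, and 18 of them differed over 2-fold (edgeR, 2919 at an unadjusted p under 0.05). DESeq2 called 1136 genes, 860 of them shared. Each library held 1 genotype, and counts summed per library called 0 genes in edgeR (1071 of 15253 at an unadjusted p under 0.05, lowest adjusted p = 0.0838, that of Eif2ak3), while limma with the library as a random effect called 19. Leaving out week 0, 8 or 12 gave 514, 2208 and 406 genes.

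**Figure D2:**
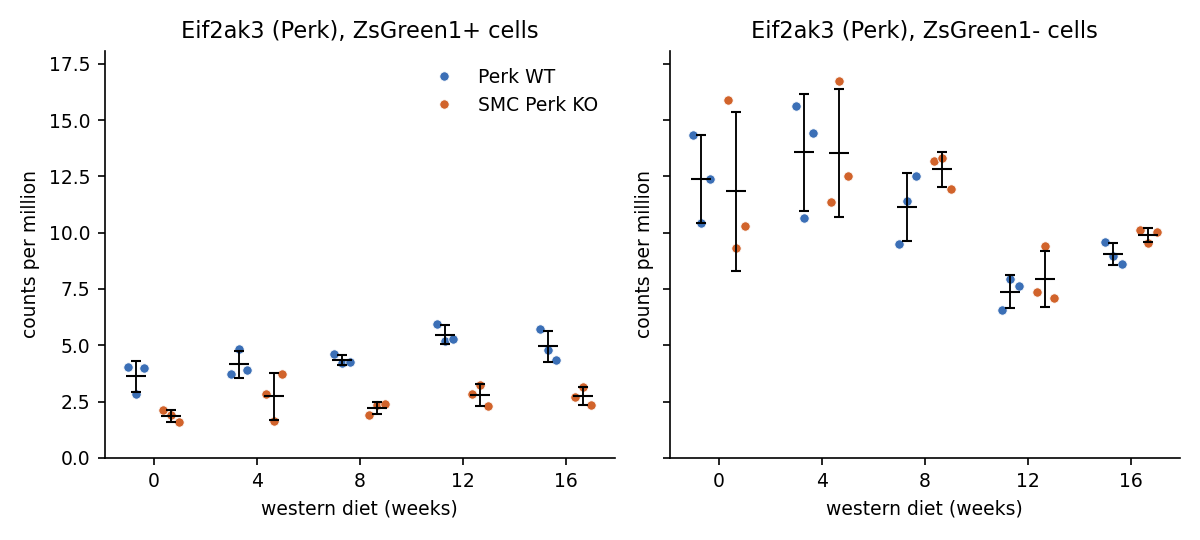
Eif2ak3 in CPM against weeks of western diet, in ZsGreen1+ (left) and ZsGreen1- (right) cells. Each point is 1 mouse, and black marks with bars give the mean and SD of a genotype and week. Over all weeks, WT and KO mice average 4.51 and 2.47 CPM in the ZsGreen1+ sort. In the ZsGreen1- sort they average 10.7 and 11.2 CPM.

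Each of 18 gene lists was compared with all other genes in the same contrast. ER chaperones and degradation factors, targets of the ATF6 and XBP1 branches of the unfolded protein response, were higher in KO mice as a group, with 3 of 32 genes passing over all genes and 6 when adjusted over the list alone (camera adjusted p = 1.54e-05, adjusted p = 0.747 with an estimated correlation). They included Dnajc3 (0.17, SE 0.04), which inhibits Perk, and the lectin chaperone Calr (0.16, SE 0.05). Oxidative phosphorylation was higher, with 11 of 53 genes passing (14 adjusted over the list alone, camera adjusted p = 5.10e-05, adjusted p = 0.747 with an estimated correlation). Ndufb2 (0.17, SE 0.04) and Cox6c (0.17, SE 0.04) of the respiratory chain were among them. The contractile apparatus was higher, with 2 of 27 genes passing (4 adjusted over the list alone, adjusted p = 0.0230, adjusted p = 0.747 with an estimated correlation). They were Myocd (0.32, SE 0.07), the master coactivator of contractile genes, and Actg2 (0.26, SE 0.07), an enteric smooth muscle actin.

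Cholesterol efflux and lipid handling, the targets of LXR, was lower in KO mice, with 3 of 22 genes passing (6 adjusted over the list alone, adjusted p = 0.00883, adjusted p = 0.747 with an estimated correlation). Among them were Scd2 (-0.33, SE 0.08), a fatty acid desaturase, and Srebf1 (-0.27, SE 0.07), a regulator of lipid synthesis. The cartilage list was lower with 0 of 24 genes passing, and 0 adjusted over the list alone (adjusted p = 2.16e-05, adjusted p = 0.747 with an estimated correlation). Chondrocyte-like cells, which carry such transcripts, numbered 74 of 4913 cells in WT and 3 of 6625 in KO mice at week 12. At week 16 they numbered 57 of 5627 and 74 of 5705. Cholesterol synthesis was lower with 0 of 24 passing and 0 adjusted over the list alone (adjusted p = 0.0262, adjusted p = 0.747 with an estimated correlation). The lysosome and foam cell list was lower with 1 of 26 passing, the macrophage elastase gene Mmp12 (-1.91, SE 0.57), and 0 adjusted over the list alone (adjusted p = 0.00129, adjusted p = 0.747 with an estimated correlation). ZsGreen1+ macrophage-like cells, which carry such transcripts, averaged 0.554% of cells in WT and 0.339% in KO mice (permutation p = 0.290). None of these 7 list calls held with an estimated correlation or by fry, a rotation test of each list by itself.

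The targets of ATF4, the transcription factor that Perk activates, were not lower as a group, with 0 higher and 3 lower of 36 genes (1 and 4 adjusted over the list alone, camera adjusted p = 0.563). The 3 lower genes were Asns (log2 fold change -0.89, SE 0.19, adjusted p = 0.00511) and Phgdh (-0.25, SE 0.06), enzymes of asparagine and serine synthesis, and Atf5 (-0.19, SE 0.05), a stress transcription factor. The other 10 lists did not pass either. Immediate early and dissociation genes had 3 of 23 higher, Hsph1, Hspa8 (0.34, SE 0.07) and Hsp90aa1 (0.25, SE 0.06), with 3 higher and 3 lower adjusted over the list alone (adjusted p = 0.0965). The modulated SMC and fibrotic matrix list had 0 of 29 genes passing (adjusted p = 0.461), interferon response 0 of 27 (0.165) and complement 0 of 14 (0.563), and for all 3 the count adjusted over the list alone was also 0. NRF2 targets had 2 of 25 lower (0.0999) and antigen presentation 1 of 15 lower (0.169), or 3 and 1 adjusted over the list alone. Apoptosis genes had 2 of 22 higher and 2 lower on both counts (0.318). In 3 lists the test and the members differed in sign. Inflammatory cytokines had 1 of 24 higher, Nfkbia (0.42, SE 0.10), with a median of -0.08 and a mean of -0.14 but an upward test (0.867). The TGF-beta response had 1 of 25 higher, Smad7 (0.37, SE 0.08), with a median of -0.03 and a mean of -0.02 under an upward test (0.757). Cell cycle genes had 1 of 35 lower with a median and mean of 0.01 and 0.01 under a downward test (0.582), and all 3 single genes also passed adjusted over the list alone.

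Contractile SMC-like cells were compared alone to ask which differences lie within that class, whose clusters differed in share between the genotypes at week 16 (cluster 2 at 21.1% of ZsGreen1+ cells in WT and 8.73% in KO mice). Eif2ak3 was lower in KO mice (2.18 ± 0.676 against 3.79 ± 0.752 CPM, log2 fold change -0.78, SE 0.12, adjusted p = 0.000181, n = 15 each). Zbtb16 (log2 fold change 0.78, SE 0.14, adjusted p = 0.000739), Klf15 (0.61), Chordc1 (0.55), Dnaja1 (0.53) and Id1 (0.66) were again higher. They were joined by Tent5b (log2 fold change 0.81, SE 0.17, adjusted p = 0.00240), a poly(A) polymerase, Nfkbia (0.60), the inhibitor of NF-kB, Ahsa2 (0.53), an Hsp90 cochaperone, Myoz2 (0.58), and the small heat shock protein gene Hspb1 (0.52). Igsf9 (log2 fold change -0.83, SE 0.13, adjusted p = 0.000277), Ide (-0.66), Anxa4 (-0.53), Ppm1m (-0.75), Igfbp5 (-0.57), Smim5 (-0.55), Rrad (-0.55), Krt18 (-0.46) and Abca1 (-0.43), the cholesterol exporter, were lower. Of the cartilage list, Comp (log2 fold change -0.62, SE 0.14, adjusted p = 0.00603), Cytl1 (-1.05) and Col2a1 (log2 fold change -2.03, SE 0.58, adjusted p = 0.0321) were lower. Col2a1 turned to 0.13 without week 12, the week at which chondrocyte-like cells numbered 74 in WT and 3 in KO mice. Stray transcripts from those cells were not separated from expression in contractile cells.

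In contractile cells, 1037 of 12286 genes passed, 547 higher and 490 lower in KO mice (edgeR, 2879 at an unadjusted p under 0.05), against 1113 in DESeq2, 2 on library sums and 46 in limma with the library. Of these, 693 were also called in all ZsGreen1+ cells, with the same sign for all 693 and 72.0 expected by chance, from overlapping cells. Leaving out weeks 0, 8, 12 or 16 gave 642, 2581, 622 and 540 genes. Of the 18 lists, 4 were higher. They were ER chaperones (4 of 31 genes, 4 adjusted over the list alone, adjusted p = 6.51e-05) and oxidative phosphorylation (11 of 53, 13 adjusted over the list alone, 6.51e-05), as well as the contractile apparatus (4 of 27, 4 adjusted over the list alone, 0.0307) and immediate early genes (3 of 23, 3 higher and 1 lower adjusted over the list alone, 0.0203). Each had an adjusted p = 0.596 with an estimated correlation. The contractile genes passing were Myocd (0.34, SE 0.06), Ldb3 (0.17, SE 0.04), Cnn1 (0.15, SE 0.04) and Actg2 (0.26, SE 0.07). The ATF4 targets had 4 of 34 genes lower, led by Asns (log2 fold change -1.07, SE 0.26, adjusted p = 0.00864), with 5 higher and 6 lower adjusted over the list alone (adjusted p = 0.948). The other 13 lists did not pass. In them, LXR targets had 4 genes lower (6 adjusted over the list alone), and cartilage and NRF2 targets 3 lower each. Interferon response had 1 higher and 2 lower, antigen presentation 2 lower, cell cycle 1 lower, apoptosis 2 higher and 2 lower, inflammatory cytokines and the TGF-beta response 1 higher each, and the remaining 4 lists 0, all with equal counts adjusted over the list alone. Their adjusted p ran from 0.0608 to 0.965, and medians and means differed in sign for complement (0.04 and -0.03) and inflammatory cytokines (-0.01 and 0.11).

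Modulated SMC-like cells were compared in the 14 KO and 12 WT mice with at least 20 such cells. The 4 mice left out were all of week 0, 3 WT and 1 KO, so the CPM means cover unlike weeks, whereas the test has week as a factor. Eif2ak3 was lower in KO mice (2.52 ± 1.97 against 6.68 ± 2.46 CPM, log2 fold change -1.30, SE 0.18, adjusted p = 0.000852). Higher were F5 (13.3 ± 16.8 against 5.86 ± 5.87 CPM, log2 fold change 1.38, SE 0.24, adjusted p = 0.0159), coagulation factor V, and Klf15 (log2 fold change 0.65, SE 0.13, adjusted p = 0.0237). So were Rock1 (log2 fold change 0.42, SE 0.06, adjusted p = 0.000949), a kinase of cytoskeletal contraction, Spsb1 (0.64), which tunes TGF-beta receptors, and Pcgf5 (0.37), a Polycomb protein. Lower were Anxa4 (log2 fold change -0.56, SE 0.10, adjusted p = 0.00992), the sialyltransferase gene St3gal4 (-0.44) and Nudt2 (-0.37). Of 10420 genes, 13 passed, 6 higher and 7 lower (edgeR, 977 at an unadjusted p under 0.05), and all 13 were also called with the same sign in all ZsGreen1+ cells, whose sums contain these cells. DESeq2 called 57, library sums 6 and limma with the library 4. The count ran from 6 to 64 when single mice were left out (without KO 2 of week 12 and KO 1 of week 16) and from 5 to 95 when single weeks were (12 and 16).

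Macrophage-like ZsGreen1- cells lie outside the lineage in which Perk was deleted, and were compared to ask whether Perk loss in SMC alters neighbouring cells. The clusters of this class differed in share between the genotypes at week 8, cluster 7 at 6.93% of ZsGreen1- cells in WT and 1.87% in KO mice and cluster 3 at 2.37% and 0.725%. Eif2ak3 was 6.51 ± 3.10 CPM in KO and 7.42 ± 2.44 CPM in WT mice (log2 fold change 0.02, SE 0.11, adjusted p = 0.992, n = 15 each), so the means and the fit differ in sign. Higher in KO mice were Fkbp5 (61.7 ± 43.5 against 23.3 ± 14.1 CPM, log2 fold change 1.23, SE 0.21, adjusted p = 0.00194), a glucocorticoid-induced cochaperone, Ccnd3 (log2 fold change 0.63, SE 0.09, adjusted p = 0.000609), a cyclin, Rcan1 (0.54), a calcineurin inhibitor, Tppp3 (0.82), Gda (0.59), Jdp2 (0.53) and Ang (0.56). The matrix genes Sparc (0.78), Mgp (0.57) and Dcn (0.54), which mark stromal cells, were higher as well. Lower in KO mice were Lpl (331 ± 230.1 against 531 ± 438 CPM, log2 fold change -0.63, SE 0.13, adjusted p = 0.0135), the lipoprotein lipase, Slc40a1 (log2 fold change -0.85, SE 0.18, adjusted p = 0.0200), the iron exporter, and Mgll (-0.82), a lipase of monoglycerides. So were Gstp1 (-0.68), Pira2 (-0.71), Pqlc1 (-0.57), Txnl4a (-0.53), Ly9 (-0.49), Anxa4 (-0.62) and Ide (-0.43). Of 10477 genes, 67 passed, 37 higher and 30 lower (edgeR, 1459 at an unadjusted p under 0.05), while DESeq2 called 175, library sums 1 and limma with the library 22. Of the 67, 13 were also called in ZsGreen1+ cells, 11 with the same sign, against 3.87 expected if the comparisons were independent. Both sorts come from the same mice, so they are not. Without week 12, 3 genes passed, and leaving out single mice gave 27 (WT 1 of week 12) to 158 (WT 2 of week 16).

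Fibroblast-like and endothelial-like ZsGreen1- cells had few differences between the genotypes, with shared genes. In fibroblast-like cells (n = 15 each) Hsph1 was higher in KO mice (34.9 ± 14.9 against 20.3 ± 6.08 CPM, log2 fold change 0.69, SE 0.13, adjusted p = 0.0207). Ide (log2 fold change -0.61, SE 0.08, adjusted p = 6.99e-05), Cirbp (log2 fold change -0.50, SE 0.09, adjusted p = 0.00440), a cold-inducible RNA-binding protein, and Zbtb8os (-0.27) were lower. In endothelial-like cells (n = 14 each) Hsph1 (log2 fold change 0.67, SE 0.13, adjusted p = 0.0408) and P4ha2 (0.61), a collagen prolyl hydroxylase, were higher. Cirbp (log2 fold change -0.51, SE 0.10, adjusted p = 0.0408) and Anxa4 (-0.47) were lower there. Eif2ak3 was 14.8 ± 3.28 CPM in KO and 13.4 ± 3.90 CPM in WT fibroblast-like cells (log2 fold change 0.08, SE 0.10, adjusted p = 0.858), and 13.2 ± 7.24 and 9.26 ± 4.59 CPM in endothelial-like cells (log2 fold change 0.32, SE 0.20, adjusted p = 0.763). In all, 8 of 11186 genes passed in fibroblast-like cells, 1 higher and 7 lower (1238 at an unadjusted p under 0.05, 41 in DESeq2, 1 on library sums), and all 8 were called with the same sign in ZsGreen1+ cells (0.561 expected if independent, which sorts of the same mice are not). In endothelial-like cells 5 of 8551 passed, 2 higher and 3 lower (639 at an unadjusted p under 0.05, 14 in DESeq2, 3 on library sums), 3 of them shared with fibroblast-like cells. Leaving out week 8 raised the counts to 132 and 25 genes, and without week 0 or 12 endothelial-like cells had 0 in edgeR.

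Whether the genotype effect depends on the week was tested by an interaction in ZsGreen1+ sums. The smallest p values belonged to small ribosomal and mitochondrial proteins, named after their values were seen: Rps29 (adjusted p = 7.15e-20), Rps28 (3.71e-18) and Rpl38 (3.71e-18) of the ribosome, and Ndufb1-ps (8.77e-19) and Atp5k (3.24e-17) of the respiratory chain. Rps29 had a KO minus WT log2 ratio of 0.71 at week 0, -1.73 at week 4, 0.16 at week 8, 0.12 at week 12 and 0.01 at week 16. Each of these ratios compares 1 library of each genotype, summed over its 3 mice, and has no spread between mice. Fkbp5 differed between weeks as well (adjusted p = 0.000223), whereas Eif2ak3 did not pass (0.785), with KO minus WT log2 ratios of -0.86, -0.68, -1.05, -0.89 and -0.80 at weeks 0, 4, 8, 12 and 16. In total 5228 of 13956 genes passed (edgeR, 6477 at an unadjusted p under 0.05, 4903 in DESeq2), and 1495 without week 8. Across 5746 genes of contractile SMC-like cells, which are not independent replicates, the KO to WT ratios of week 8 had a Spearman rho of -0.412 to 0.235 with those of the other weeks (median -0.359, 4 pairs). Among the other weeks rho was 0.0874 to 0.579 (median 0.239, 6 pairs). Each genotype of a week is 1 library, so a difference of libraries and one of genotype by week cannot be told apart.

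**Figure D3:**
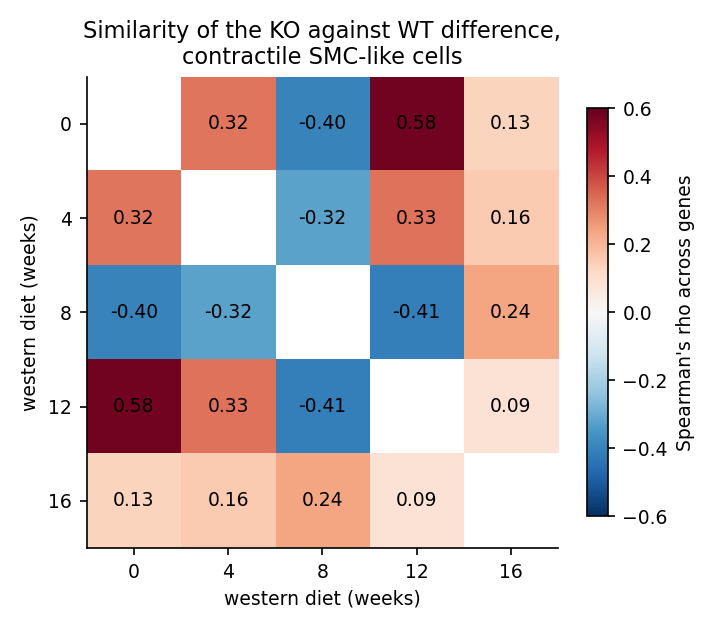
Spearman's rho across genes between the KO to WT log2 ratios of each pair of weeks in contractile SMC-like cells. Colour and printed value give rho, from -0.412 (weeks 8 and 12) to 0.579 (weeks 0 and 12).

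The interaction of genotype with sort asks which genotype effects belong to the SMC lineage, where Perk was deleted. Eif2ak3 led, whose genotype effect in ZsGreen1+ minus ZsGreen1- cells was -0.91 on the log2 scale (SE 0.11, adjusted p = 1.12e-06, n = 15 mice per genotype and sort). In Fjx1 (log2 fold change 0.89, SE 0.16, adjusted p = 0.00733), a secreted kinase of the Fat pathway, Kif3a (0.36), a motor protein of cilia, Phb (0.29), a mitochondrial scaffold, and Mcur1 (0.24), a regulator of mitochondrial calcium uptake, the effect was higher in ZsGreen1+ cells. Of 15416 genes, 7 passed, 6 with a higher and 1 with a lower effect (edgeR, 1446 at an unadjusted p under 0.05), against 32 in DESeq2, 2 on library sums and 2 in limma with the library. This main fit took the 2 sums of a mouse as independent, although each mouse gave both sorts. With the animal as a block, which keeps that pairing, 36 genes passed. Without week 16 the main fit gave 98.

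Week 16 was compared with week 0 in 6 mice each, adjusted for genotype. The 6 mice of a week came from 1 library per genotype and sort. Week cannot be separated here from the age of the animals or the preparation of the libraries, so these changes are not those of disease alone. In ZsGreen1+ cells the modulated markers Vcam1 (1453 ± 188 against 24.6 ± 4.90 CPM, log2 fold change 5.76, SE 0.20, adjusted p = 6.26e-19; ENSMUSG00000027962, chromosome 3, 116109949 to 116129688), an adhesion molecule for leukocytes, and Spp1 (5069 ± 2885 against 7.39 ± 6.29 CPM, log2 fold change 9.29, SE 0.85, adjusted p = 2.32e-10), osteopontin, rose (mean ± SD, n = 6 each). The proteoglycan gene Lum (log2 fold change 7.07, SE 0.38, adjusted p = 5.54e-15) rose too. Ly6a (8.94), the stem cell antigen Sca1, Prg4 (10.55), lubricin, and Ctss (9.04), a cysteine protease, also rose. Col2a1, the cartilage collagen, reached 116 ± 90.7 CPM at week 16 from 0 counts in the 6 mice of week 0, at least 3391-fold higher against a floor of 3 counts over the group. Hp and Slurp1, also at 0, were at least 4550.4 and 1930.2-fold higher. The acute phase genes Lcn2, Serpina3n and Saa3 reached 831 ± 356, 279.6 ± 101 and 174 ± 135 CPM at week 16, from 1, 3 and 4 counts in all week 0 sums. The greatest fall was that of Ccnb1ip1 (1.55 ± 0.584 against 74.5 ± 28.1 CPM, log2 fold change -5.79, SE 0.49, adjusted p = 4.27e-11), a ubiquitin ligase of meiosis. Carmn (log2 fold change -2.07, SE 0.11, adjusted p = 4.39e-15), the long noncoding RNA of contractile SMC, Optc (-2.07), a matrix proteoglycan, Tcap (-1.90), telethonin, Nrgn (-2.04), Cidea (-1.99), a lipid droplet protein, Krt18 (-1.84) and Idi1 (-1.76), of cholesterol synthesis, fell too. Of 13672 genes, 8755 passed, 4587 higher and 4168 lower (edgeR, 9158 at an unadjusted p under 0.05). With the share of modulated cells as a covariate 2017 passed.

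Of the 18 lists, 16 passed between weeks 16 and 0 in ZsGreen1+ cells, 13 upward and 3 downward. The estimated correlation ended all 16 calls, with an adjusted p = 0.101 to 0.434 with an estimated correlation. The modulated SMC and fibrotic matrix list rose in 25 of 29 genes (camera adjusted p = 6.32e-12), inflammatory cytokines in 23 of 24 (8.40e-09), such as Cxcl12 (2.36, SE 0.14), and complement in 14 of 14 (1.10e-05), such as C3 (8.82, SE 0.49) and C4b (7.70, SE 0.32). Interferon response rose in 25 of 27 genes (3.91e-08), antigen presentation in 15 of 15 (4.79e-05), lysosome and foam cell in 25 of 26 (4.39e-07), and LXR targets in 20 of 22 (1.72e-05), among them the cholesterol exporters Abca1 (2.65, SE 0.20) and Abcg1 (3.37, SE 0.27). ZsGreen1+ macrophage-like cells, which carry antigen presentation and lysosome transcripts, went from 0.0170% to 1.36% of cells in WT and from 0.0218% to 0.969% in KO mice. Within contractile cells neither of those lists passed (adjusted p = 0.615 and 0.263). The cartilage list rose in 20 of 24 genes (21 adjusted over the list alone, 0.00291), with Sox9 at 3.40, SE 0.28. Cell cycle genes rose in 33 of 35 (1.96e-05), with Mki67 at 4.76, SE 0.68. Cycling cells went from 0% to 0.267% of the pooled ZsGreen1+ cells in WT and from 0.091% to 0.193% in KO mice. Within contractile cells the cell cycle list did not pass (camera adjusted p = 0.624). The ATF4 targets, which report on the integrated stress response, rose in 25 and fell in 6 of 36 genes (0.00241), with Gdf15 at 3.53, SE 0.26 and Asns at 2.56, SE 0.33, and ER chaperones rose in 21 of 32 (0.000676), with Calr at 0.66, SE 0.07. In contractile cells alone, neither the ATF4 targets nor the ER chaperones passed (camera adjusted p = 0.301 and 0.611). The rise of these 2 lists was not separated from the larger share of modulated cells at week 16. The TGF-beta response rose in 15 and fell in 2 of 25 genes (0.000607), with Thbs1 at 5.69, SE 0.30. It did not pass in contractile cells alone (0.181), nor did LXR targets (0.263) or the cartilage list (0.311). Immediate early genes rose in 10 and fell in 4 of 23 (0.0301). Cholesterol synthesis fell in 22 of 24 genes (4.75e-09), with Fdps at -1.69, SE 0.12, oxidative phosphorylation in 44 of 53 (2.70e-16) and the contractile apparatus in 20 of 27 (4.46e-06), with Myl9 at -1.30, SE 0.10. NRF2 targets (14 of 25 higher, 6 lower, 0.0502) and apoptosis genes (13 of 22 higher, 2 lower, 0.0666) did not pass. Apart from cartilage, and NRF2 targets with 7 lower, the counts adjusted over the list alone were the same.

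**Figure D4:**
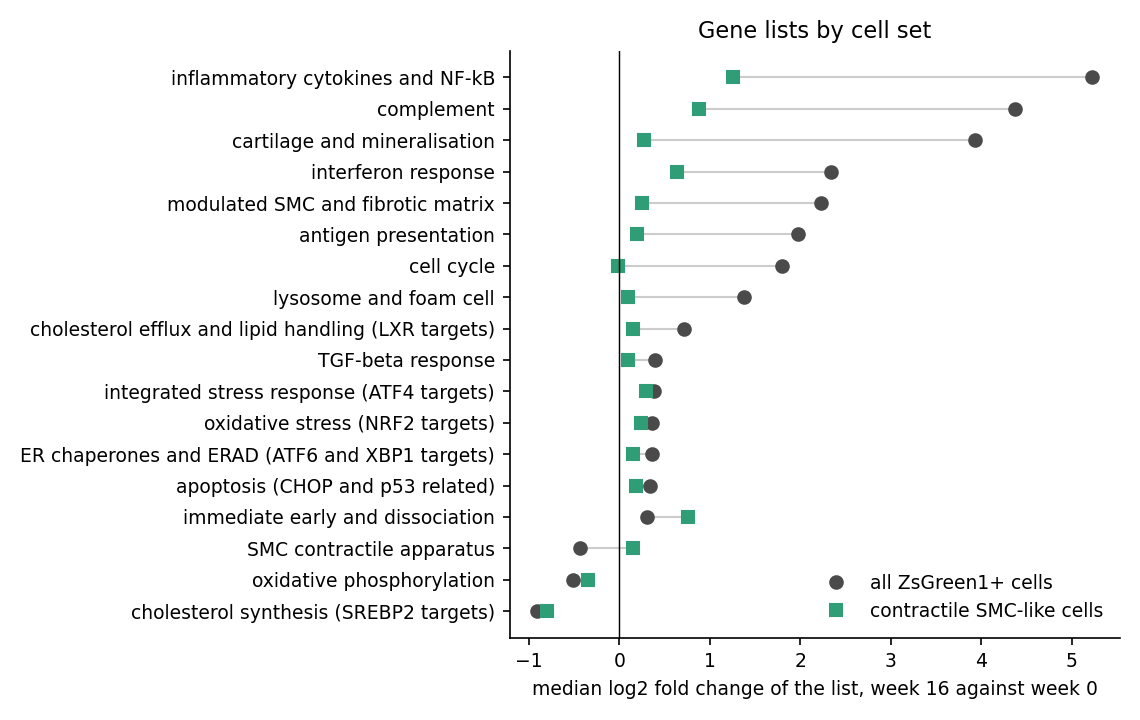
Median log2 fold change of week 16 against week 0 for each of 18 lists. Circles mark the median in all ZsGreen1+ cells, -0.91 for cholesterol synthesis and -0.52 for oxidative phosphorylation. Squares mark the median in contractile SMC-like cells, -0.80 and -0.34 for the same lists. A grey line joins the circle and square of a list.

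Within contractile SMC-like cells, week 16 against week 0 compares cells of unlike clusters. Clusters 0 and 4 made up 47.4% and 26.4% of ZsGreen1+ cells in WT and 42.6% and 29.0% in KO mice at week 0. At week 16 they made up 1.72% and 1.37% in WT and 1.27% and 0.823% in KO mice. Cluster 8 went from 0.308% to 11.4% in WT and from 0.422% to 22.5% in KO mice, and cluster 2 from 1.62% to 21.1% and from 1.20% to 8.73%. Vcam1 (58.1 ± 20.8 against 7.79 ± 1.56 CPM, log2 fold change 2.80, SE 0.17, adjusted p = 2.85e-14) and Hes1 (log2 fold change 2.46, SE 0.20, adjusted p = 2.95e-11), a Notch target, rose (n = 6 each). So did Hk2 (2.33), a hexokinase, Igfbp5 (2.23), the nuclear receptor gene Nr4a2 (2.16), Sncg (2.11), Fosb (2.06) and Dcn (1.87), decorin. Modulated cells, led by Vcam1, went from 0.638% and 1.05% to 25.3% and 25.7% of the same libraries. Their stray transcripts were not separated from expression in contractile cells, for these genes or for the modulated list below. Ccnb1ip1 (log2 fold change -5.79, SE 0.52, adjusted p = 1.13e-10), the circadian factor gene Dbp (-2.05), Hmgn2 (-1.92), Nrgn (-1.81), Pcolce2 (-1.66), Carmn (-1.53), Fdps (-1.38) and Mfap5 (-1.38), a microfibril protein, fell. Of 12286 genes, 6266 passed, 3236 higher and 3030 lower (edgeR, 6914 at an unadjusted p under 0.05), against 2652 on library sums and 3904 in limma with the library. Of the lists, 7 passed. Cholesterol synthesis fell in 22 of 24 genes (adjusted p = 5.00e-07, adjusted p = 0.190 with an estimated correlation) and oxidative phosphorylation in 42 of 53 (7.71e-12, adjusted p = 0.247 with an estimated correlation). Inflammatory cytokines rose in 11 of 16 genes (0.000203, adjusted p = 0.142 with an estimated correlation), complement in 5 of 7 (0.00260, adjusted p = 0.142 with an estimated correlation) and interferon response in 13 of 22 (0.00297, adjusted p = 0.267 with an estimated correlation). Immediate early genes rose in 15 of 23 (0.000133, adjusted p = 0.395 with an estimated correlation). The modulated list rose in 15 and fell in 6 of 29 genes (0.0116, adjusted p = 0.319 with an estimated correlation). For these 7 lists the counts adjusted over the list alone were the same. The contractile apparatus, with 14 higher and 10 lower of 27 genes, did not pass (0.364), nor did the other 10 lists, with adjusted p from 0.116 to 0.683.

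In macrophage-like ZsGreen1- cells, Fabp5, a fatty acid binding protein, rose between weeks 0 and 16, at 10132 ± 2108 against 6.04 ± 3.57 CPM (log2 fold change 10.99, SE 0.64, adjusted p = 2.65e-14, n = 6 each). Ctsk, a collagen-cleaving cathepsin, Npy and Igf2r had 0 counts at week 0 and were at least 43.5, 38.9 and 14.6-fold higher at week 16. Gpnmb reached 1795 ± 491 CPM from 2 counts. Pf4 (358 ± 168 against 4781 ± 845 CPM, log2 fold change -3.49, SE 0.25, adjusted p = 3.11e-12), Lyve1 (log2 fold change -3.44, SE 0.45, adjusted p = 2.56e-07), the hyaluronan receptor, Timd4 (-4.19), a receptor for apoptotic cells, Ccl24 (-4.22) and Retnla (-3.66) fell. No gene list was tested in these cells. The class held unlike clusters at the 2 weeks. Clusters 3 and 7 were at 0% of ZsGreen1- cells at week 0 and at 11.7% and 9.17% in WT and 11.5% and 8.15% in KO mice at week 16. Cluster 8 stayed at 2.76% and 2.59% in WT and 2.38% and 2.42% in KO mice, while the class grew. The other classes shifted too. Of the fibroblast-like clusters, cluster 1 went from 29.3% to 3.94% in WT and from 28.2% to 2.37% in KO mice, and cluster 2 from 8.13% to 7.82% and from 10.3% to 8.21%. Of the endothelial-like clusters, cluster 9 went from 7.56% to 1.93% and from 7.17% to 1.39%, and cluster 15 from 0% to 1.70% and from 0% to 1.64%. The changes below therefore mix cluster make-up with expression. In fibroblast-like cells (n = 6 each) the innate defence genes Lcn2 (437 ± 211 against 1.23 ± 0.627 CPM, log2 fold change 8.40, SE 0.79, adjusted p = 4.34e-10) and Lrg1 (7.06) and the chemokine genes Cxcl14 (6.66), Cxcl2 (5.74) and Ccl7 (5.25) rose. Saa3 was at least 2178-fold higher. Eln (686 ± 103 against 2435 ± 323 CPM, log2 fold change -1.90, SE 0.20, adjusted p = 5.93e-09), elastin, Rbp4 (-2.52) and Tnmd (-3.25) fell. C1qb, a macrophage gene, rose in these fibroblast-like sums from 0.967 ± 0.703 to 37.4 ± 8.87 CPM. In endothelial-like cells (6 mice at week 16 and 5 at week 0) Ccl2, a monocyte chemokine, Igfbp3, Tgfbi and Spp1 had 0 counts at week 0 and were at least 295, 146, 131 and 103-fold higher. Stray transcripts of other cells were not separated from expression for these 4 genes. Dbp (log2 fold change -3.64, SE 0.31, adjusted p = 1.19e-10) and the basement membrane gene Col4a4 (-2.98) fell. In edgeR 3544 of 10477 genes passed in macrophage-like cells (2064 higher, 1480 lower), 4557 of 11186 in fibroblast-like cells (2273 higher, 2284 lower) and 3362 of 8551 in endothelial-like cells (1774 higher, 1588 lower). The macrophage-like sums of week 0 were small, down to 20 cells and 103637 counts in a mouse.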

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

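The tests of exchanged labels at week 8, and of short coding sequences and short transcripts at week 4, were chosen only after the result was seen, as were the exchanges of whole libraries. Because the effect of genotype differed between groups, 3 results are set out here. These are 5228 genes whose genotype effect differed between weeks in ZsGreen1+ cells, 7 genes whose effect differed between the sorts, and Eif2ak3, whose effect in ZsGreen1+ minus ZsGreen1- cells was -0.91 on the log2 scale. The fit behind the 7 genes ignored that each mouse gave both sorts, and with the animal as a block 36 genes passed. A result outside the comparisons of the report was 1388 cells with modulated SMC markers in the ZsGreen1- sort.

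Genotype labels were exchanged among mice within weeks in 40 splits, the real one included. In contractile cells the real split called 1037 genes and the highest other 1, and in macrophage-like cells 67 and 2. In fibroblast-like cells they called 8 and 3, and in endothelial-like cells 5 and 2. Thus 1 of the 40 splits, the real one, reached each count, the smallest share that 40 splits can give. This argues against chance only if the mice of a library are independent. The same held for the interactions of genotype with week (5228 and 1776, 1 split) and with sort (7 and 3, 1 split). In all ZsGreen1+ cells 2 of 40 splits called as many as the real 884 (highest other 1297), and in modulated cells 3 did (13 and 99), so chance was not excluded there. The 99 calls of another split, several times the real count, point to a structure of the samples. As many lists as the real 7 in ZsGreen1+ cells came up in 25 splits (highest other 13), and as many as the real 4 in contractile cells in 12 (highest other 11), which does not exclude chance. Such exchanges mix the mice of 2 libraries and say nothing about differences between libraries. Exchanging whole libraries within weeks gives 16 splits, too few for a share under 0.05. Their real and highest other counts were 884 and 3470 in ZsGreen1+ cells, 1037 and 3547 in contractile, 13 and 98 in modulated and 5 and 23 in endothelial-like cells (all with week 8 exchanged), 67 and 122 in macrophage-like cells (week 4), and 8 and 234 in fibroblast-like cells (weeks 4 and 8). With the real split included, 5 of the 16 reached the real count in ZsGreen1+, 5 in contractile and 8 in modulated cells. In macrophage-, fibroblast- and endothelial-like cells 3, 7 and 4 did. In contractile cells the KO to WT ratios of week 8 ran against those of weeks 0, 4 and 12, as set out below. Higher counts with week 8 exchanged can follow from such reversed ratios. They cannot tell a structure of the samples from an effect of genotype at that week.

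With labels of weeks 0 and 16 exchanged within genotypes, 1 of 40 splits, the real one, reached the real count in each class. This argues against chance only if the mice of a library are independent. The real and highest other counts were 8755 and 6316 in ZsGreen1+ cells, 6266 and 3196 in contractile, 3544 and 560 in macrophage-like, 4557 and 1988 in fibroblast-like and 3362 and 2098 in endothelial-like cells. For the lists chance was not excluded, with 9 splits reaching the 16 lists of ZsGreen1+ cells (highest other 17) and 10 reaching the 7 of contractile cells (highest other 11).

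A first pattern is the 884 genes called between genotypes in ZsGreen1+ cells. A different share of modulated cells was argued against, as 98.1% of the calls stayed with their sign when that share was a covariate. That share differed by only -0.426 points between the genotypes, so the covariate could remove few calls. Shares of other clusters were not used as covariates, so other differences in cell make-up were not tested. Of the 883 calls other than Eif2ak3, 2.49% lay within 20 Mb of it on chromosome 6, against 1.38% of the genes tested. These were 22 calls, Anxa4 and Klf15 among them, and 188 genes tested (Fisher's exact test, two-sided p = 0.00646, BH-adjusted p = 0.0388 over 6 tests). In contractile cells the shares were 2.03% and 1.45% and did not pass (Fisher's exact test, p = 0.103, adjusted p = 0.131). In modulated cells 2 of the 12 calls other than Eif2ak3 lay there (adjusted p = 0.0400). Macrophage-, fibroblast- and endothelial-like cells did not pass (adjusted p = 0.230, 0.131 and 0.131). Of the 18 linked calls also tested in fibroblast-like ZsGreen1- cells, 14 had the same sign. The agreement of the other calls was not computed, and both sorts come from the same mice, so this count does not bear on linkage. From the excess near the gene, variants carried along with the modified Perk gene are a candidate explanation for some of these 22. How far the carried segment extends, and whether it acts on genes elsewhere, was not tested. On library sums 70.0% of the calls kept an unadjusted p under 0.05 and their sign, which had been set beforehand to count against library differences, but that bound was wrong, because the calls were picked on the same mice, simulated library deviations gave 918 false calls of 1100, and edgeR on library sums called 0 (1071 genes at an unadjusted p under 0.05, 1136 in DESeq2 and 19 in limma with the library on mice). For the calls as a set, an effect of Perk loss and library differences therefore cannot be told apart with 5 libraries per genotype. The 19 genes that limma called with the library as a random effect are all among the 884 with the same sign. They come from the same sums, so this adds no support, and 40 of 185 such limma calls were false with simulated library deviations. Eif2ak3 was lower in KO mice in each of the 5 weeks, so libraries are less of a doubt for that gene.

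A second pattern is week 8, where the genotype ratios of contractile cells ran against those of weeks 0, 4 and 12, with rho of -0.412 to 0.235 over its 4 pairs of weeks. Exchanged genotype labels were argued against by Eif2ak3, which at week 8 was lower in KO mice by a log2 ratio of -1.05 (SE 0.12, n = 3 each), as in the other weeks. Handling of the week 8 animals might move all cell types alike, and the week 8 ratios of contractile and fibroblast-like cells had a rho of 0.187 across genes, against 0.0821 to 0.216 in the other weeks, which lies between the bounds set beforehand. With macrophage-like cells rho was 0.251 at week 8 against -0.108 to 0.0501 in the other weeks, and with endothelial-like cells 0.278 against 0.0293 to 0.186, which goes with that explanation. The ZsGreen1+ cells of the KO mice also stood apart at week 8, with a median depth of 15696 UMIs per kept cell (mean over 3 mice) against 9799 in WT mice and 7799 to 12265 in KO mice of the other weeks. Over the mitochondrial limit were 24.7% of their cells, against 16.6% in WT mice. These signs of quality were not tested as a cause. Preparation of week 8 and a true effect of genotype at that time cannot be told apart, since the week was 1 library per genotype and sort.

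The last pattern is that small ribosomal and mitochondrial genes led the interaction with week. The ratios given here each compare 1 library of each genotype. At week 4 the KO minus WT log2 ratio in ZsGreen1+ cells was -1.73 for Rps29, -1.36 for Rps28, -1.33 for Rpl38, -1.50 for Ndufb1-ps and -1.67 for Atp5k, and Rps29 stood at 0.21 in the ZsGreen1- cells of the same mice. A lower yield of all transcripts with coding sequences of up to 360 nt at week 4 was argued against by their median ratio of 0.00662 (295 nonribosomal genes). For nonribosomal genes a different size range of cDNA at week 4 was argued against by transcripts of up to 600 nt. Their median ratio was 0.0145 with quartiles of -0.066 and 0.045 (24 nonribosomal genes, Atp5k among them). The 8 ribosomal genes of such length deviated by a median of -0.0920 in the KO and 0.375 in the WT library of week 4. For these it stays open. Among 5866 genes of known length with a mean log2 CPM of at least 4, 42 were that short. Of the 50 smallest interaction p values among the 5866, 12 belonged to such short genes. For other weeks a different size range in single libraries could still apply. The median deviation of these 24 genes was 0.57 in the KO library of week 0, which met the bound set beforehand, but 0.31 in the WT library of that week, a comparison added after the value was seen, so this stays open. No biological explanation for this pattern was tested.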

How the results depend on the processing

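The settings with clusters 5 and 6 counted as modulated, the animal as a block, the weeks taken apart, other class boundaries, removal of high doublet scores, and single mice left out for the shares were chosen only after the result was seen. Over 23 results, 550 of 672 values kept their direction and their side of the threshold or stayed within 1.5 times the count, 112 moved, 9 reversed and 1 became stronger. Of 10623 values of single named genes, 9368 kept both, 1231 fell short of the threshold, 1 newly passed and 23 reversed. The cause was not tested for any value below unless one is given.

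Sums per library lowered the genotype counts of genes, though not those of lists given below. They called 0 genes in edgeR in ZsGreen1+ cells (1071 at an unadjusted p under 0.05, 1136 in DESeq2 on mice), 2 in contractile, 6 in modulated, 1 in macrophage-like, 1 in fibroblast-like and 3 in endothelial-like cells and 2 for the interaction with sort, with 10 sums per sort in place of 30. limma with the library as a random effect called 19, 46, 4, 22, 3 and 7 in the same order and 2 for the interaction with sort. Week 16 against week 0 in contractile cells called 2652 genes on library sums and 3904 in limma with the library, against 6266.

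DESeq2 called 57 genes in modulated, 175 in macrophage-like, 41 in fibroblast-like and 14 in endothelial-like cells and 32 for the interaction with sort. Without a filter on low counts these were 369, 569, 143, 186 and 2, from 13, 67, 8, 5 and 7. The animal as a block, with the hashtag taken as the animal, gave 36 genes for the interaction with sort. Weeks 0, 4 and 8 alone gave 167 genes between genotypes in ZsGreen1+ cells, 138 in contractile, 10 in macrophage-like and 2 in fibroblast-like cells and 23 for the interaction with sort. Weeks 12 and 16 alone gave 485 in ZsGreen1+, 22 in macrophage-like and 75 in fibroblast-like cells and 2 for the interaction, all with fewer mice. The share of modulated cells as a covariate left 2017 of the genes between weeks 16 and 0 in ZsGreen1+ cells by count, since that share rises with week.

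With clusters 5 and 6 counted as modulated, the genotype difference of the modulated share reversed to 2.22 points. Values near 0 also reversed. Myh11 in ZsGreen1+ cells, from 0.00, was -0.00610 with the covariate and -0.0806 in weeks 12 and 16. Eif2ak3 in macrophage-like cells, from 0.02, was -0.0219 on library sums and -0.00722 in limma with the library. Eif2ak3 in fibroblast-like cells, from 0.08, was -0.0244 in weeks 0, 4 and 8. With correlations estimated per list, camera called 0 lists in all 4 contrasts, from 7 and 4 between genotypes and 16 and 7 between weeks 16 and 0 in ZsGreen1+ and contractile cells, and fry called 0, 2, 18 and 14.

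Leaving out single mice gave 638 to 995 genes between genotypes in ZsGreen1+, 834 to 1131 in contractile, 6 to 64 in modulated, 27 to 158 in macrophage-like, 5 to 21 in fibroblast-like and 0 to 13 in endothelial-like cells, 4600 to 5574 for the interaction with week and 4 to 25 for that with sort. Leaving out single weeks gave 406 (week 12) to 2208 (week 8), 540 (16) to 2581 (8), 5 (12) to 95 (16), 3 (12) to 92 (16), 5 (0, 12 and 16) to 132 (8), 0 (0 and 12) to 25 (8), 1495 (8) to 5491 (16) and 10 (0) to 98 (16), in the same order. For endothelial-like cells 639 genes had an unadjusted p under 0.05 in edgeR with all weeks, and DESeq2 called 14. Between weeks 16 and 0, leaving out single mice gave 8400 to 8656 genes in ZsGreen1+, 5831 to 6194 in contractile, 3009 to 3598 in macrophage-like, 4186 to 4470 in fibroblast-like and 2875 to 3423 in endothelial-like cells.

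For the genotype differences in shares, single mice gave -1.51 to 0.370 points for modulated, -0.406 (KO 1 of week 16, permutation p = 0.0476) to -0.134 for chondrocyte-like and -1.87 to 0.264 for macrophage-like cells. Single weeks gave -0.759 to 0.379 (week 12), -0.377 to 0.0717 (week 12) and -1.87 to 0.695 (week 8). Rho with week stayed within 0.965 to 0.977, 0.764 to 0.809 and 0.884 to 0.904 without single mice, and within 0.942 to 0.964, 0.606 to 0.799 and 0.797 to 0.883 without single weeks. Among single genes, Myh11 in ZsGreen1+ cells ran from -0.0226 to 0.0301 without single mice and from -0.0597 to 0.0318 without single weeks. Eif2ak3 in macrophage-like cells ran from -0.0197 to 0.0639 and from -0.0889 to 0.0852. The value for Col2a1, genotype effect in contractile SMC-like cells, ran from -2.49 to -1.57 without single mice and from -2.05 to 0.129 (week 12) without single weeks. Library sums and limma with the library were not run for the interaction with week, where each genotype and week is 1 library. Depth limits the macrophage-like sums of week 0 and the endothelial-like sums, down to 103637 and 112395 counts in a mouse tested.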

Other observations

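No tests are given in this part, and its genes and classes were chosen only after the result was seen. Asns, the asparagine synthetase and a target of ATF4 downstream of Perk, climbed with diet in ZsGreen1+ cells of WT mice, from 1.40 ± 0.0875 CPM at week 0 to 6.52 ± 3.51 CPM at week 8 and 13.1 ± 2.62 CPM at week 16 (mean ± SD, n = 3 each). In KO mice Asns stood at 1.18 ± 0.201, 3.10 ± 1.02 and 4.96 ± 0.873 CPM at the same weeks. In ZsGreen1- cells its mean reached 9.85 CPM in WT and 6.42 CPM in KO mice at week 16.

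Anxa4, the membrane-binding protein gene near Eif2ak3, stood higher at the later weeks in both genotypes, with the larger step in WT mice. In ZsGreen1+ cells it ran from 43.1 to 58.0 CPM in the 6 WT mice of weeks 0 and 4 and from 70.3 to 126 CPM in the 9 WT mice of weeks 8 to 16, against 39.0 to 71.7 CPM in all 15 KO mice. The KO means were 39.5, 52.2, 59.3, 64.1 and 69.4 CPM at weeks 0, 4, 8, 12 and 16. In ZsGreen1- cells the ranges were 60.8 to 78.7, 117 to 224 and 59.5 to 157 CPM. Ide, the insulin-degrading enzyme, ran from 19.7 to 47.9 CPM in KO and from 30.3 to 58.9 CPM in WT mice in ZsGreen1+ cells. At week 8 Ide stood at 40.6 ± 6.47 CPM in KO and 39.7 ± 5.95 CPM in WT mice.

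Fkbp5, a glucocorticoid-induced gene, stood in ZsGreen1+ cells at 6.74 ± 0.543, 19.2 ± 4.59, 7.41 ± 2.60, 34.5 ± 4.69 and 13.6 ± 6.91 CPM in KO mice at weeks 0, 4, 8, 12 and 16. In WT mice it stood at 1.88 ± 0.529, 7.08 ± 5.37, 17.2 ± 8.08, 6.67 ± 0.993 and 6.72 ± 0.751 CPM (n = 3 each). In ZsGreen1- cells Fkbp5 was 46.8 ± 7.10, 91.8 ± 9.62, 28.5 ± 4.73, 41.5 ± 5.64 and 24.5 ± 7.17 CPM in KO mice. WT mice had 22.6 ± 5.25, 40.2 ± 17.3, 37.8 ± 8.18, 14.3 ± 3.26 and 13.4 ± 0.793 CPM. KO was higher than WT at weeks 0, 4, 12 and 16 and lower at week 8 in both sorts. Ccnb1ip1 did not fall steadily with diet. In ZsGreen1+ cells it was 64.8 ± 34.2, 43.9 ± 17.2, 1.81 ± 1.37, 37.7 ± 13.2 and 1.93 ± 0.601 CPM in WT mice at these weeks. KO mice had 84.1 ± 22.9, 11.2 ± 7.72, 3.80 ± 0.796, 29.3 ± 10.4 and 1.18 ± 0.278 CPM.

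The 1388 ZsGreen1- cells with modulated SMC markers made up 7.93 ± 1.63% of ZsGreen1- cells in KO and 3.21 ± 0.499% in WT mice at week 12, and 3.29 ± 1.66% and 6.38 ± 6.68% at week 16 (n = 3 each), with at most 0.106% in any group before. Of these 1388 cells, 11.2% were among the highest 5% of doublet scores of their library, against 5.53% of all cells. Doublets among them were not separated. ZsGreen1 stood at 40.3 CPM in these cells, against 5159 CPM in ZsGreen1+ modulated cells and 33.9 CPM in ZsGreen1- fibroblast-like cells. A ZsGreen1 count was found in 39.8% of them at a median depth of 14997.5 counts, and in 15.9% of fibroblast-like cells at 5832.5. With all cells thinned to 5000 counts the share was 16.9%, against 6.75% in macrophage-like, 18.6% in endothelial-like and 99.6% in ZsGreen1+ modulated cells. The 234 macrophage-like cells of the ZsGreen1+ sort had 495 CPM of ZsGreen1 and a ZsGreen1 count in 52.6% of cells at a median depth of 12672.5, against 11.5% at 7553 in ZsGreen1- macrophage-like cells. Thinned to 5000 counts in the same way, the shares were 31.2% and 6.75%.

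Other classes shifted with week as well, given as group means without a test. From week 0 to week 16 contractile cells went from 93.2% to 48.2% of ZsGreen1+ cells in WT and from 91.0% to 45.8% in KO mice. Fibroblast-like cells went from 76.7% to 23.5% of ZsGreen1- cells in WT and from 83.2% to 21.3% in KO mice, and monocyte-like cells from 1.21% to 8.29% and from 0.503% to 9.10%.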
